A study of Mus musculus with 2 samples.

How the data were processed

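Single-nucleus RNA sequencing was done on whole olfactory bulbs of adult male C57Bl/6N mice, 18 weeks old. The labels give 1 group with 2 biological replicate libraries, called library 1 and library 2 here. Each library was made from 3 bulbs: frozen tissue was opened in a Dounce homogenizer, 3 nuclear isolations were pooled, and 100000 events of the DAPI-stained singlet gate were sorted before capture in 10x Genomics droplets and sequencing of the 3' ends of transcripts, per the labels' protocols. Animals within a library cannot be told apart, so the tests between classes rest on 2 pools. Their main model takes out a shift common to all classes of a library, and the scatter left is shared over all classes in the model. Tests and intervals on counts of UMIs or nuclei do not measure the spread between pools.

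The deposited values are raw UMI counts per gene and nucleus in a matrix already filtered to barcodes called as cells; a UMI (unique molecular identifier) stands for 1 captured RNA molecule. Cell Ranger 6.1.2 and the build GRCm39 are named in the submitters' processing notes. Whether intron reads were counted, which annotation release was used and how reads matching several genes were treated is not given in the sources used here. The files pair each gene identifier with a symbol, for 22581 genes. A reference table on another assembly (GRCm38.p6, NCBI RefSeq) held 22476 of these identifiers and was used only for the order of neighbouring genes, so coordinates are not printed.

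Library 1 held 5635 barcodes and 35122364 UMIs, with a median of 5258 UMIs and 2171 genes per barcode and a range from 501 to 51909 UMIs. Library 2 held 7528 barcodes and 41800111 UMIs, with a median of 4785 UMIs and 1996 genes and a range from 503 to 44868 UMIs. Barcodes with under 500 genes were removed (27 and 36), and the limit of 5% mitochondrial UMIs removed none, since mitochondrial genes held 0.00766% and 0.0109% of UMIs. Scrublet, run per library at an expected rate of 6%, called 156 and 225 barcodes doublets (2.78% and 3.00%), which were removed, leaving 5452 and 7267 nuclei. The gene totals of the libraries differed by more than sampling noise (chi-square per degree of freedom 10.3 over 15174 genes), so the libraries were counted as separate samples.

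Nuclei of both libraries were clustered together with scanpy 1.11.5 on Python 3.11.15: counts were scaled to 10000 per nucleus and log-transformed, 1999 variable genes were taken, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 32 clusters, with seed 1 and no batch correction. The 1904 genes of 12 gene lists were left out of the clustering. The lists held neuropeptide precursors, peptide receptors, steroid and metabolic hormone signalling, monoamine and acetylcholine receptors, glutamate receptors, GABA and glycine receptors, potassium channels, a joint list of sodium, calcium, HCN and TRP channels, chemoreceptors (1474 genes), chemosensory transduction, GnRH neuron development and regulation, and immediate early genes. Clusters were named from fixed marker genes, as classes that are only like a cell type, because no annotation of the nuclei was used. A marker counted when it reached 5 CPM (UMIs scaled to the same total) and at least 2 times its level in all other nuclei (for GABAergic subtypes, in the other GABAergic clusters), and a name needed at least 3 markers and 50% of its list. A GABAergic or granule-like name needed at least 4 markers above the geometric midpoint between low and high clusters. These scoring thresholds were set after the clusters were seen, whereas the markers, the gene lists, the edgeR comparisons of classes and the rule for named genes were fixed before the data were examined.

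Counts were summed per library and class, and the 12 classes with at least 20 nuclei in each library entered 1 model (24 sums, 11698 genes after edgeR's filter on low counts, 11 residual degrees of freedom). The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM normalization, library as a block and Benjamini-Hochberg adjustment over all genes tested, at 0.05. Because each class is measured in the same 2 libraries, the libraries pair the classes: nuclei of a library come from the same pool of animals. Log2 fold changes are given with a standard error derived from the F statistic, and CPM values as mean ± SD over 2 libraries. CPM of genes tested across classes or in single clusters rest on UMI totals scaled by TMM. CPM of naming markers, of summed genes, of genes with too few counts for their test and of sensory neuron-like nuclei rest on raw UMI totals. Values on these 2 scales cannot be added or set against each other directly. The genes named per contrast are the 10 list genes, chemoreceptors apart, with the largest fold change in each direction among those past the test, in the same direction in both libraries and at 10 CPM or more in the higher class. Gnrh1, Gnrhr, Kiss1r, Esr1, Esr2, Pgr and Nos1 were to be named whatever their values. A few genes that these rules select are not reported here. Where a class held 0 UMIs of a gene, the fold is a lower bound against 3 counts over the class sum; with 1 to 3 UMIs the ratio of counts per total UMIs is given with its exact interval and no fitted fold. Fold changes of single libraries come from log2 CPM with a prior count added, which pulls low genes toward 0.

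The test was checked on simulated sums with 200 changed genes, where 11386 genes entered for the mitral and tufted-like contrast. In the data, 83 of 232 list genes were called higher and 90 lower in that contrast. Far fewer genes were thus changed in the simulated sums than the calls in the data point to. The rates describe the simulated sums and need not hold for the contrasts. For the mitral and tufted-like contrast 76.3% of 2-fold and 86.0% of 4-fold changes were recovered; the values were 70.0% and 87.9% for the dopaminergic contrast, 41.1% and 84.0% for the neuroblast contrast and 25.0% and 70.7% for the ensheathing contrast, with 5.88%, 2.48%, 3.15% and 2.08% false calls in the same order.

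Shares of nuclei carry 95% exact Clopper-Pearson intervals, and a share of 0 is given with the limit that 3 counts allow; both cover counting error only. Droplets also hold free RNA from broken nuclei, so shares of nuclei with a UMI are set beside those in glia-like and vascular-like classes. For depth, nuclei were also thinned to 2000 UMIs. Nuclei with a Gnrh1 UMI were compared with nuclei of the same library and class whose UMI totals lay within 25% of theirs. The alternatives were RLE size factors, the DESeq2 Wald test (DESeq2 1.42.0), no filter on low counts, no library block, a model of only the 2 classes compared, equal numbers of nuclei (94 per class and library) at equal depth, clustering at resolutions 0.5 and 2.0, 4000 variable genes, called doublets kept, minimums of 200 and 1000 genes, other UMI thresholds and matching for Gnrh1, and leaving out each library. A test of list genes in single clusters, against the mean of the other clusters with at least 15 nuclei in each library, was chosen after the data were examined.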

Results

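The data were UMI counts from single nuclei of the olfactory bulb of adult male mice, in 1 group of 2 replicate libraries, each a pool of 3 bulbs. After filtering, library 1 held 5452 nuclei with a median of 5217 UMIs and library 2 held 7267 nuclei with a median of 4730 UMIs. Gene totals of the libraries correlated with r = 0.997 across genes, which are not independent replicates. The title of the series names neurons of the bulb that make gonadotropin-releasing hormone (GnRH), the peptide that drives the reproductive axis, and links them to social odours and reproductive behaviour in male mice. The design holds no treated or second group, so the comparisons were those between classes of nuclei within the same libraries. They were where Gnrh1 was found, whether nuclei with it held chemoreceptor RNA, and how peptide, hormone, transmitter, channel and chemoreceptor genes differed between classes.

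Inhibitory neurons made up most of the nuclei. Granule-like nuclei, the axonless inhibitory neurons of the deep bulb, were 63.2% ± 0.212 of nuclei (mean ± SD, n = 2 libraries, 8047 nuclei), and carried Synpr, Meis2 and Tshz1 in each of their 10 clusters. Prox1, another marker on the granule list, did not count in any of them, and Meis2 is also on the wider GABAergic list. The name was given only to GABAergic clusters that took no subtype name. Other GABAergic interneuron-like nuclei were 18.3% ± 0.805. Dopaminergic periglomerular-like nuclei, the interneurons around the glomeruli that make dopamine, were 2.72% ± 0.0707 (345 nuclei) and carried Th, Ddc, Slc18a2, Slc6a3, Nr4a2 and Etv1. Mitral and tufted-like nuclei, the output neurons of the bulb, were 2.83% ± 0.130 (361 nuclei, in clusters 22, 24 and 29) with Slc17a7, Slc17a6, Cdhr1 and Tbr1 in each cluster, Tbx21 in clusters 22 and 29 and Eomes in clusters 22 and 24. Neuroblast-like nuclei, in which the listed markers Sox11, Sox4, Igfbpl1 and Cd24a counted but Dcx did not, were 1.69% ± 0.330 (211 nuclei). Cortical glutamatergic-like nuclei, with Neurod6, Neurod2 and Emx1, were 191 nuclei.

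Among glia-like classes, olfactory ensheathing-like nuclei, which wrap the axons of sensory neurons, were 1.86% ± 0.330 (232 nuclei) and carried all 6 of their markers (Frzb, Mybpc1, Prss56, Matn2, Fabp7 and Sox10). Oligodendrocyte-like nuclei were 2.92% ± 0.889, astrocyte-like nuclei 2.27% ± 0.658, microglia and macrophage-like nuclei 1.23% ± 0.282, mixed vascular and fibroblast-like nuclei 0.649% ± 0.0358 and oligodendrocyte precursor-like nuclei 0.349% ± 0.104. A cluster of 33 nuclei carried all 7 markers of olfactory sensory neurons (Omp, Gng13, Stoml3, Cnga2, Rtp1, Rtp2 and Gng8). It came from library 1 alone, where it was 0.605% of nuclei (95% exact interval 0.417 to 0.849), against 0 of 7267 nuclei in library 2, which allows a share of up to 0.0413%. A further 16 nuclei led by ribosomal protein genes had no name.

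**Figure D1:**
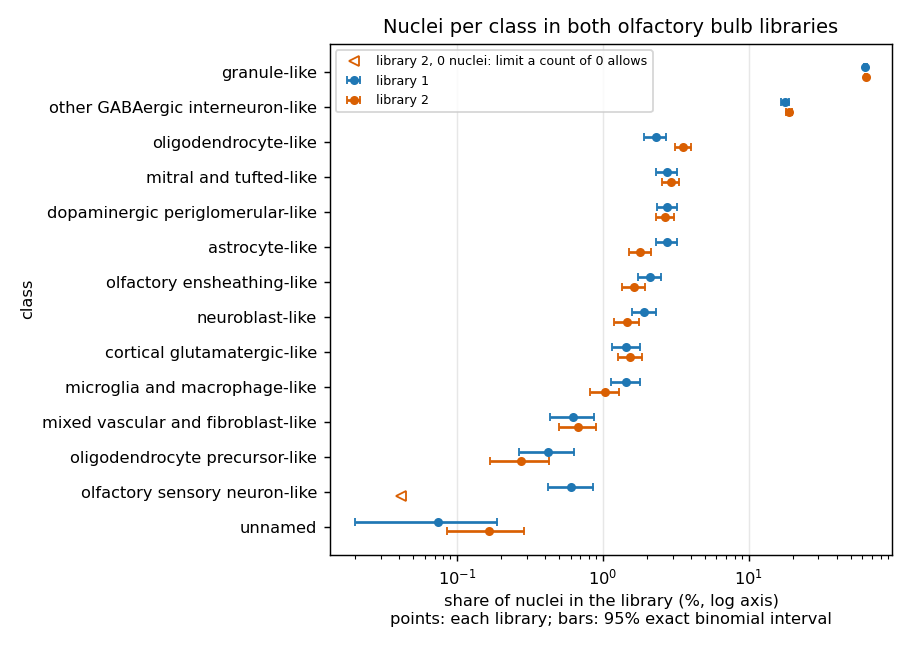
Share of nuclei per class as percent of all nuclei kept, on a log axis; points are the libraries, bars are 95% exact binomial intervals, and the open triangle is the limit that a count of 0 allows. Granule-like nuclei take 63.2% and other GABAergic interneuron-like nuclei 18.3%, and olfactory sensory neuron-like nuclei are seen in library 1 alone.

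The first question was which class held Gnrh1 (ENSMUSG00000015812), since the peptide is the product by which GnRH neurons are defined. Gnrh1 UMIs were rare and lay in neuron-like and glia-like classes alike. A Gnrh1 UMI was found in 31 of 5452 nuclei of library 1 (0.569%, 95% exact interval 0.387 to 0.806) and 17 of 7267 nuclei of library 2 (0.234%, 0.136 to 0.374), a mean of 0.401% ± 0.237. The 48 nuclei held 50 UMIs of the gene in all, at most 2 in a nucleus, and were spread over 20 of the 32 clusters. Cluster 3, of granule-like nuclei, held the largest number, 5 of its 818 nuclei.

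By class, Gnrh1 was found in 3 of 361 mitral and tufted-like nuclei (0.831%, interval 0.172 to 2.41), 26 of 8047 granule-like nuclei (0.323%, 0.211 to 0.473), 11 of 2341 other GABAergic interneuron-like nuclei (0.470%, 0.235 to 0.839). It was also found in 2 of 191 cortical glutamatergic-like nuclei (1.05%, 0.127 to 3.73; median depth 14129 UMIs) and 1 of 345 dopaminergic periglomerular-like nuclei. Of glia-like nuclei, 2 of 232 ensheathing-like, 2 of 383 oligodendrocyte-like and 1 of 43 oligodendrocyte precursor-like nuclei held it. No UMI was found among 211 neuroblast-like nuclei, which allows a share of up to 1.42%, or among 280 astrocyte-like nuclei, which allows 1.07%. Classes that should lack the peptide were taken as the background, though their UMIs were not shown to be free RNA. In glia-like and vascular-like nuclei together, 5 of 1174 held a UMI (0.426%, 0.138 to 0.991, median depth 2777 UMIs). Of neuron-like nuclei, 43 of 11496 held 1 (0.374%, 0.271 to 0.504, median depth 5168 UMIs). In CPM, Gnrh1 stood at 1.61 in glia-like and vascular-like nuclei and 0.633 in neuron-like nuclei. The neuron-like share lay below the background share and within its interval, so it was read as background. Expression above it was not detectable over these classes as a whole at this depth. The interval rests on 5 nuclei, and a few expressing nuclei would hardly move a share of 11496. The comparison thus cannot decide whether a rare population of GnRH neurons is present. With nuclei thinned to 2000 UMIs, which left out 170 and 235 nuclei, Gnrh1 was found in 9 of 5282 and 7 of 7032 nuclei.

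**Figure D2:**
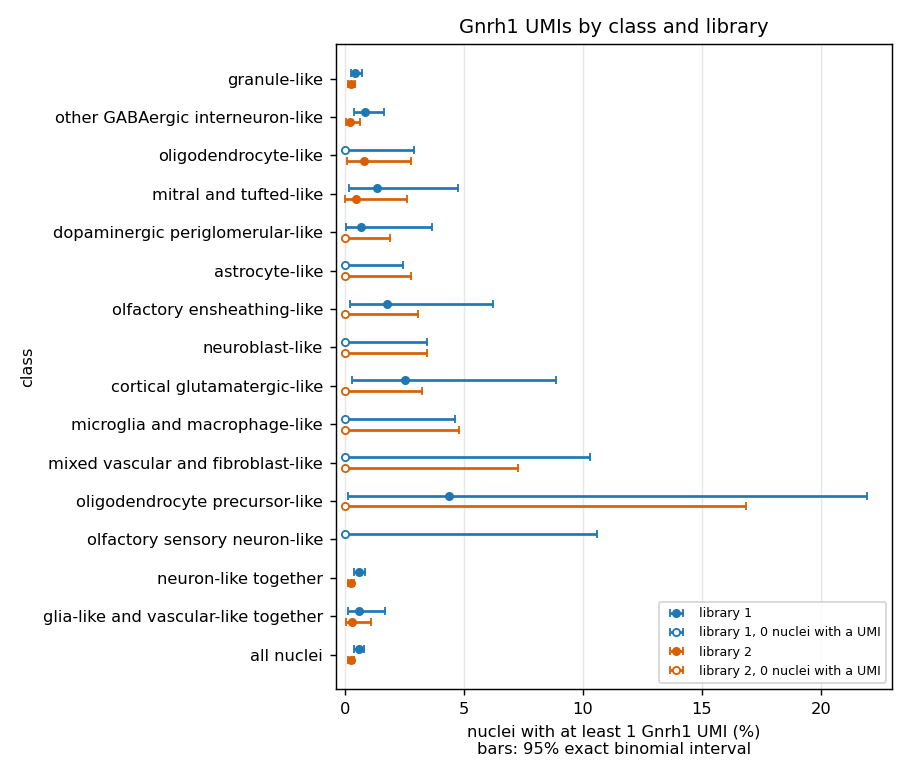
Percent of nuclei with at least 1 Gnrh1 UMI in each class; points are the libraries (open where the count is 0) and bars are 95% exact binomial intervals, for counting error only. Neuron-like nuclei together stand at 0.572% and 0.227%, beside 0.574% and 0.307% for glia-like and vascular-like nuclei together.

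Of the genes of GnRH and kisspeptin signalling, the GnRH receptor gene Gnrhr gave 1 UMI, in an ensheathing-like nucleus. Kiss1r, the receptor through which kisspeptin acts on GnRH neurons, was found in 138 nuclei (65 of 5452 and 73 of 7267, or 1.19% and 1.00%). Its share was 3.32% in mitral and tufted-like and 2.61% in dopaminergic periglomerular-like nuclei, against 0.511% in glia-like and vascular-like nuclei (median depths 11104, 6070 and 2777 UMIs). Other GABAergic interneuron-like nuclei held it in 40 of 2341 (1.71%, median depth 3929 UMIs) and cortical glutamatergic-like nuclei in 5 of 191 (2.62%, median depth 14129 UMIs). In CPM, which allows for depth, Kiss1r stood at 2.67 in mitral and tufted-like, 3.83 in dopaminergic, 4.14 in other GABAergic, 1.67 in cortical and 1.42 in granule-like nuclei. Glia-like and vascular-like nuclei stood at 1.61 CPM (6 UMIs), so shares in the deeper classes overstate their distance from it. In class sums Kiss1r stood at 2.65 against 1.43 CPM in mitral and tufted-like against granule-like nuclei and at 3.89 against 1.43 CPM in the dopaminergic comparison. Gnrh1, Gnrhr, Kiss1r and Esr2 had too few counts for the test across classes.

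The next question was whether nuclei with a Gnrh1 UMI also held RNA of the receptors by which the nose detects odours and pheromones. In library 1, 21 of 31 such nuclei (67.7%, 95% exact interval 48.6 to 83.3; median depth 6979 UMIs) held a chemoreceptor UMI, against 57.3% of nuclei of the same class and depth. In library 2 it was 9 of 17 (52.9%, 27.8 to 77.0; median depth 6423 UMIs) against 49.3%. The difference, 10.5 and 3.67 percentage points (mean 7.06 ± 4.80), left the matched share inside the interval of the Gnrh1 nuclei in both libraries. Since the Gnrh1 shares of the wider classes lay at background, a UMI alone was not taken to mark a nucleus as that of a GnRH neuron. The comparison describes nuclei with the UMI only. UMIs of the chemosensory transduction list were in 28 of 31 nuclei (90.3%) of library 1, against 89.6% of matched nuclei. In library 2 it was 15 of 17 (88.2%) against 89.5%. The list holds widely found genes such as Pde1c (12901 and 13953 UMIs over all barcodes of libraries 1 and 2) and Gnao1 (8741 and 11262). Most matched nuclei were thus positive, which leaves little room for a higher share, and a UMI of the list does not mark a sensory neuron. Trpc2, Cnga4 and Cngb1, channel genes of pheromone and odour sensing neurons, were found in 0 of 31 and 0 of 17 nuclei. That allows up to 9.68% and 17.6%, and matched nuclei held them at 0.414% and 0.101%. Over all barcodes of libraries 1 and 2, Trpc2 gave 0 and 0 UMIs, Cnga4 9 and 1 and Cngb1 36 and 6. At matched shares this low, so few nuclei would rarely hold such a UMI. The counts of 0 thus cannot show a lower share, and speak only against shares above these limits.

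Mitral and tufted-like nuclei were compared with granule-like nuclei to set the output neurons of the bulb against its main interneurons. Among peptide and hormone receptor genes, mitral and tufted-like nuclei were higher in Rxfp1, the relaxin receptor (87.3 ± 9.53 against 0.898 ± 0.726 CPM; mean ± SD, n = 2 libraries; log2 fold change 6.50 ± 0.27, ± SE), in Npr1, a natriuretic peptide receptor (6.35 ± 0.34), and in Qrfpr, the receptor of the peptide QRFP (21.2 ± 6.22 against 0.875 ± 0.0711 CPM; 4.54 ± 0.40). They were lower in Oprd1, the delta opioid receptor (4.09 ± 1.60 against 96.6 ± 10.0 CPM; -4.56 ± 0.28), Npffr2, a receptor of RFamide peptides (-4.45 ± 0.24), Vipr2, a receptor of vasoactive intestinal peptide (17.6 ± 2.49 against 328 ± 1.11 CPM; -4.22 ± 0.18), and Tacr1, the substance P receptor (-3.98 ± 0.22). The peptide precursor Adcyap1, which encodes PACAP, was higher (21.1 ± 0.469 against 0.332 ± 0.0811 CPM; 5.80 ± 0.47). Among calcium-permeable TRP channels, both Trpc7 and Trpc5 were higher: Trpc7 stood at 351 ± 179 against 2.51 ± 1.14 CPM (7.09 ± 0.17) and Trpc5 at 415 ± 94.0 against 14.2 ± 1.56 CPM (4.86 ± 0.17).

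Of the genes of fast transmission, the glycine receptor subunit Glra3 (69.5 ± 28.9 against 0.350 ± 0.262 CPM; 7.42 ± 0.35), the NMDA receptor subunit Grin2c (5.20 ± 0.24) and the kainate receptor subunit Grik1 (1038 ± 139 against 34.0 ± 6.80 CPM; 4.94 ± 0.22) were higher in mitral and tufted-like nuclei. The kainate receptor subunit Grik3 (11.5 ± 2.96 against 261 ± 45.8 CPM; -4.50 ± 0.20), the potassium channels Kcnq5 (-4.26 ± 0.29) and Kcnk13 (-4.26 ± 0.19) and the muscarinic receptor Chrm2 (75.1 ± 35.6 against 1250.3 ± 69.4 CPM; -4.05 ± 0.19) were lower. Sema7a, a semaphorin that guides migrating GnRH neurons, was higher (5.23 ± 0.22). Gipr, a receptor of a gut hormone, gave 1 against 408 UMIs, a ratio of 41.3 (95% interval 7.37 to 1636) in favour of granule-like nuclei. Trhr, the receptor of thyrotropin-releasing hormone, gave 3 against 613 UMIs, a ratio of 20.7 (95% interval 7.05 to 101). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these 20 genes lay between 8.07e-30 for Trpc7 and 2.84e-07 for Trhr, each in the same direction in 2 of 2 libraries. Trpc7 and Glra3 were among the 10 leading genes of cluster 24 but not of clusters 22 and 29. Cluster 24 held 138 of the 361 nuclei, 48 in library 1 and 90 in library 2. The class values of these genes thus need not hold for each cluster.

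Of the sex hormone receptors and other genes fixed to be named, Pgr, the progesterone receptor, was higher in mitral and tufted-like nuclei (38.5 ± 3.51 against 20.6 ± 0.775 CPM; log2 0.91 ± 0.18), and Nos1, neuronal nitric oxide synthase (-0.98 ± 0.17), was lower. Esr1, an oestrogen receptor, stood at 3.30 against 5.39 CPM, with no call. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.53e-05 for Pgr, 5.27e-06 for Nos1 and 0.282 for Esr1. With equal numbers of nuclei at equal depth, the call of Nos1 was lost (-0.86, adjusted p = 0.444 by the same edgeR test). The DESeq2 Wald test did not call Adcyap1 (6.12, adjusted p = 0.202). Single-library values lay over 1.5-fold from the fitted value for some genes. For Glra3, Npr1 and Adcyap1 both libraries lay below the fitted value and close to each other, and the added prior count pulls such values toward 0. Without library 2 and without library 1, the log2 ratios were 6.48 and 6.61 for Glra3, 6.93 and 5.49 for Rxfp1, 5.87 and 5.61 for Npr1, 5.04 and 4.76 for Adcyap1, 4.42 and 3.71 for Qrfpr, -3.58 and -4.69 for Chrm2, -3.40 and -4.60 for Tacr1, -3.65 and -4.75 for Gipr and -5.69 and -2.78 for Trhr.

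Over the 11 lists without the chemoreceptors, 430 genes were in the files and 232 were tested. Of these, 83 were higher and 90 lower in mitral and tufted-like nuclei, and 59 were not past the threshold (84 and 93 adjusted over the list alone). Here and in the other contrasts, counts per list were not set beside the share called among all genes tested. They do not show that a list stands out from other genes. Glutamate receptors split almost evenly, with 10 of 24 higher and 12 lower (10 and 12 adjusted over the list alone). Members on either side were Grik1 and Grin2c against Grik3 and Gria3 (-3.56). GABA and glycine receptors were 8 of 19 higher and 6 lower (8 and 6 adjusted over the list alone). Gabrb2 stood at 3.35 ± 0.14 and Gabra5 at -3.70 ± 0.14. Potassium channels were 20 of 59 higher and 27 lower (20 and 27 adjusted over the list alone). Kcna2, a channel of axons, stood at 4.34 ± 0.16 and Kcnh6 at 4.32 ± 0.30. Sodium, calcium, HCN and TRP channels were 16 of 34 higher and 10 lower (17 and 10 adjusted over the list alone). Scn9a, a sodium channel of sensory neurons, stood at 4.13 ± 0.18 and Trpm2 at 4.03 ± 0.23. Monoamine and acetylcholine receptors were 5 of 16 higher and 5 lower (5 and 5 adjusted over the list alone), among them the muscarinic Chrm1 at -3.12 ± 0.29 and the serotonin receptor Htr1f at -3.26 ± 0.17. Peptide receptors were 8 of 28 higher and 11 lower (9 and 13 adjusted over the list alone).

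Peptide precursors were 3 of 9 higher and 2 lower (3 and 2 adjusted over the list alone). Cck, the precursor of cholecystokinin, stood at 28.0 ± 1.10 against 1.95 ± 0.344 CPM (3.81 ± 0.31) and the enkephalin precursor Penk at -3.15 ± 0.27. Steroid and metabolic hormone genes were 5 of 11 higher and 3 lower (5 and 3 adjusted over the list alone). The thyroid hormone receptor Thra stood at -1.09 ± 0.13 and the growth hormone receptor Ghr at -2.07 ± 0.15. Chemosensory transduction genes were 3 of 6 higher and 1 lower (3 and 1 adjusted over the list alone). Pde1c (2.24 ± 0.25), Gnal, the G protein of odour transduction (0.91 ± 0.15), and Gnai2 (0.70 ± 0.20) were higher, and Ric8b, which assists Gnal, was lower (-0.74 ± 0.12). Genes of GnRH neuron development were 6 of 17 higher and 4 lower (6 and 5 adjusted over the list alone). Ndnf stood at 3.64 ± 0.17 and the guidance factor Sema3a at 515 ± 5.99 against 88.6 ± 0.626 CPM (2.54 ± 0.12). Immediate early genes, which mark recent activity or handling, were lower for 9 of 11 and higher for 0 (0 and 11 adjusted over the list alone). Egr1 stood at 4.09 ± 1.60 against 41.5 ± 2.75 CPM (-3.34 ± 0.29). Ier2 gave 0 against 139 UMIs and was at least 4.69-fold lower against 3 counts over the class sum. For the immediate early genes higher, edgeR gave 0 at an unadjusted p under 0.05 and DESeq2 called 0.

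Chemoreceptors were the largest list, and those called in mitral and tufted-like nuclei lay in 2 stretches of genes. Of 1474 chemoreceptor genes in the files, 596 had a UMI and 12 had counts enough for the test. In it, 7 of the 12 were higher and 0 lower in mitral and tufted-like against granule-like nuclei (7 and 0 adjusted over the list alone). The odorant receptor gene Olfr111 (ENSMUSG00000090675) stood at 508 ± 82.5 against 1.23 ± 0.734 CPM (log2 fold change 8.59 ± 0.20), Olfr112 at 106 ± 18.9 against 0.149 ± 0.133 CPM (9.01 ± 0.28) and Olfr115 at 173 ± 74.7 against 0.332 ± 0.0811 CPM (8.78 ± 0.23). Olfr110 gave 80 against 2 UMIs, a ratio of 395 (95% interval 106 to 3318). The vomeronasal receptor gene Vmn1r209 (ENSMUSG00000071491) stood at 173 ± 51.0 against 0.616 ± 0.0933 CPM, Vmn1r207 at 6.67 ± 0.42 and Vmn1r206 at 5.97 ± 0.40. Adjusted p of the 7 genes lay between 9.19e-31 for Olfr111 and 9.17e-14 for Olfr110 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The DESeq2 Wald test called 3 of the 7, Olfr111, Vmn1r206 and Vmn1r209. For Olfr110, Olfr112, Olfr115 and Vmn1r207 its fold changes were also positive, with standard errors of 7.14, 7.09, 7.08 and 3.34. Without library 2 and without library 1, the log2 ratios were 9.01 and 7.72 for Olfr111, 8.07 and 7.20 for Olfr112, 8.41 and 7.28 for Olfr115, 7.81 and 7.01 for Vmn1r209, 6.44 and 5.09 for Vmn1r207 and 5.76 and 4.71 for Vmn1r206. Of genes lower, edgeR gave 0 at an unadjusted p under 0.05 and DESeq2 called 0. The filter on low counts decides which genes enter: 18 were higher and 3 lower with no filter, and 12 and 3 with only the 2 classes compared in the model. With equal nuclei and depth only 4 of the 7 genes had counts enough to be tested, and these 4 were higher.

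In the reference annotation on GRCm38.p6, Olfr110 to Olfr116 lie in 1 row, with the gene Gm18213 between Olfr114 and Olfr115, and Vmn1r206 to Vmn1r209 lie in another, with Gm11307 and Vmn1r pseudogenes between its first 3 members. Each row holds related copies that can share reads, so the split of UMIs among its genes is uncertain. CPM of the sums rest on raw UMI totals, on which Olfr111 alone stood at 410 CPM in mitral and tufted-like nuclei. As sums, Olfr110 to Olfr116 gave 3407 UMIs in mitral and tufted-like nuclei (700.1 CPM, in 33.2% of nuclei at a median depth of 11104 UMIs), against 1.56 CPM in granule-like nuclei (0.833% of nuclei, median depth 5385) and 5.36 CPM in glia-like and vascular-like nuclei (1.28% of nuclei, median depth 2777). Vmn1r206 to Vmn1r209 gave 987 UMIs (203 CPM, 39.6% of nuclei), against 2.14 CPM in glia-like and vascular-like nuclei. Within that background, microglia and macrophage-like nuclei stood apart, with 16 UMIs of the Olfr row (46.7 CPM, in 7.19% of nuclei at a median depth of 1953 UMIs) and 1 of the Vmn1r row. The clusters of the class differed, and cluster 22 held both rows (1062 and 207 CPM; 35.8% of its nuclei had UMIs of both). Cluster 24 held 372 UMIs of the Olfr row (256 CPM) and 0 of the Vmn1r row, and cluster 29 held 0 of the Olfr row and 394 of the Vmn1r row (709.9 CPM, in 81.8% of nuclei). Cluster 22 was alike in both libraries (1076 and 1045 CPM of the Olfr row), whereas cluster 24 stood at 505 CPM without library 2 and 106 CPM without library 1, and cluster 29 at 1235 and 379 CPM of the Vmn1r row. The flanking genes Olfr109, Olfr117 and H2-M2 had 0 UMIs in all nuclei, and Olfr118, Vmn1r205 and Vmn1r210 had 2, 1 and 2 in mitral and tufted-like nuclei and 2, 1 and 6 in all.

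**Figure D3:**
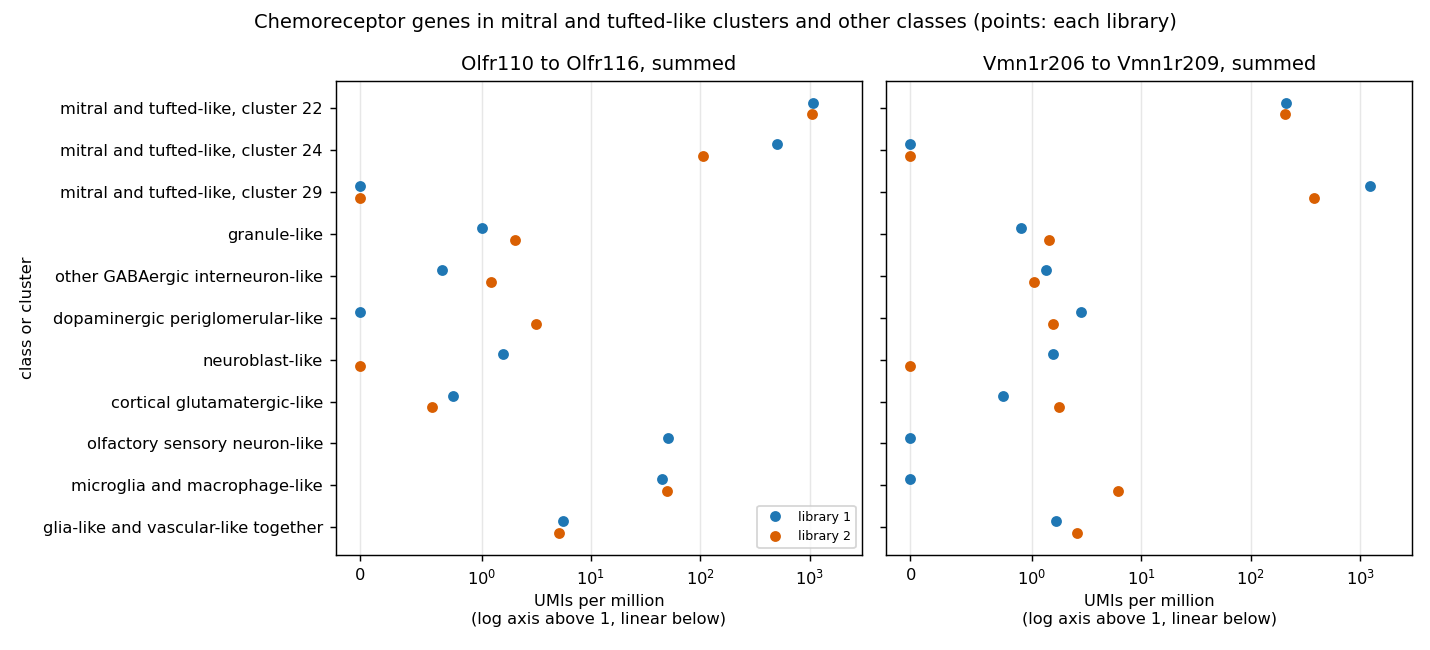
Summed CPM of Olfr110 to Olfr116 and of Vmn1r206 to Vmn1r209 in clusters 22, 24 and 29 and in other classes, on an axis that is logarithmic above 1 and linear below; points are the libraries. Cluster 22 stands high in both sums (1062 and 207 CPM over both libraries), cluster 24 in the first and cluster 29 in the second.

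Dopaminergic periglomerular-like nuclei were compared with granule-like nuclei to set these interneurons apart from the main inhibitory class. Pde1c (ENSMUSG00000004347), a phosphodiesterase that cleaves cyclic nucleotides and is also used in odour transduction, had the largest rise among the list genes named, at 3728 ± 19.5 against 22.4 ± 1.70 CPM (log2 fold change 7.38 ± 0.29). The receptors Htr7 of serotonin (424 ± 33.1 against 6.55 ± 1.96 CPM; 6.01 ± 0.15), Hcrtr2 of orexin (16.5 ± 0.550 against 0.750 ± 0.0277 CPM; 4.37 ± 0.50), Adra1b of noradrenaline (54.2 ± 10.6 against 3.92 ± 0.796 CPM; 3.78 ± 0.23) and Pth2r of parathyroid hormone-like peptides (3.29 ± 0.37) were higher. The precursor Trh, of thyrotropin-releasing hormone, stood at 24.9 ± 1.79 against 0.765 ± 0.227 CPM (4.95 ± 0.46). Grin2c (121 ± 18.3 against 1.37 ± 0.540 CPM; 6.41 ± 0.23), the sodium channel Scn7a (3.22 ± 0.33), the potassium channel Kcnj12 (3.20 ± 0.31) and Trpc7 (3.18 ± 0.34) were also higher.

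Lower in dopaminergic periglomerular-like nuclei were the glutamate receptor genes Grin2a (45.8 ± 36.9 against 1565 ± 103 CPM; -5.13 ± 0.31), Gria3 (45.3 ± 24.4 against 1510.4 ± 10.1 CPM; -5.05 ± 0.27) and Grm8 (54.1 ± 38.2 against 1528 ± 96.8 CPM; -4.87 ± 0.31). So were the potassium channels Kcnk12 (-5.55 ± 0.33), Kcnj6 (11.4 ± 5.47 against 489 ± 12.1 CPM; -5.41 ± 0.22), Kcnh3 (-4.80 ± 0.25) and Kcnh5 (21.4 ± 9.14 against 554 ± 21.8 CPM; -4.67 ± 0.23), the TRP channel Trpc4 (-4.85 ± 0.27), and the receptors Tacr1 (-5.34 ± 0.32) and Oprd1 (-4.75 ± 0.35). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the 20 genes lay between 6.41e-29 for Htr7 and 3.16e-09 for Hcrtr2, each in the same direction in 2 of 2 libraries. Nos1 was lower (7.08 ± 0.749 against 60.0 ± 3.66 CPM; -3.07 ± 0.29), and Pgr was higher (45.4 ± 1.99 against 20.6 ± 0.775 CPM; 1.14 ± 0.20); Esr1 stood at 5.52 against 5.39 CPM. Their adjusted p was 1.57e-11, 1.70e-05 and 0.985 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With equal numbers of nuclei at equal depth the call of Trpc7 was lost (0.24, adjusted p = 1 by the same edgeR test). Without library 2 and without library 1, the log2 ratios were 4.74 and 4.20 for Trh, 2.59 and 3.36 for Kcnj12, -6.74 and -4.83 for Kcnk12, -6.69 and -4.60 for Tacr1, -6.22 and -4.50 for Grin2a, -5.72 and -4.59 for Gria3, -5.73 and -4.29 for Grm8, -5.70 and -4.24 for Kcnh3 and -7.86 and -3.86 for Oprd1.

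Over the 11 lists, 59 of 232 genes were higher and 85 lower in dopaminergic periglomerular-like nuclei, and 88 were not past the threshold (63 and 92 adjusted over the list alone). Potassium channels were lower for 28 of 59 and higher for 11 (12 higher and 29 lower adjusted over the list alone). Glutamate receptors were 8 of 24 higher and 11 lower (8 and 12 adjusted over the list alone). GABA and glycine receptors were 8 of 19 higher and 4 lower (9 and 4 adjusted over the list alone). The GABA receptor subunits Gabrb2 (2.16 ± 0.15) and Gabrg3 (2164 ± 185 against 511 ± 16.7 CPM; 2.08 ± 0.22) were higher and Gabra5 was lower (-3.63 ± 0.16). Sodium, calcium, HCN and TRP channels were 13 of 34 higher and 10 lower (13 and 10 adjusted over the list alone). Monoamine and acetylcholine receptors were 4 of 16 higher and 7 lower (5 and 7 adjusted over the list alone). Adrb1, a receptor of noradrenaline, gave 0 against 242 UMIs and was at least 3.95-fold lower against 3 counts over the class sum. Peptide receptors were 6 of 28 higher and 6 lower (7 and 6 adjusted over the list alone). Of Trhr, dopaminergic and granule-like nuclei held 2 against 613 UMIs, a ratio with a 95% interval from 4.14 to 124 in favour of granule-like nuclei; without library 2 and without library 1 the log2 ratios were -5.69 and -2.63.

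Of chemosensory transduction genes, 5 of 6 were higher and 0 lower (5 and 0 adjusted over the list alone). Beside Pde1c, these included Gnal (140.2 ± 17.0 against 47.7 ± 3.79 CPM; 1.56 ± 0.16), Adcy3, the adenylyl cyclase of odour transduction (1.49 ± 0.15), and Gnai2 (0.80 ± 0.25). Peptide precursors were 1 of 9 higher and 4 lower (1 and 4 adjusted over the list alone). Penk stood at -3.86 ± 0.37 and the granin Scg2 at -1.20 ± 0.21. Steroid and metabolic hormone genes were 1 of 11 higher and 4 lower (1 and 4 adjusted over the list alone), the glucocorticoid receptor Nr3c1 among them at -1.90 ± 0.23. Genes of GnRH neuron development were 2 of 17 higher and 5 lower (2 and 7 adjusted over the list alone). The chromatin remodeller Chd7 stood at 1.38 ± 0.12. Immediate early genes were lower for 6 of 11 and higher for 0 (0 and 8 adjusted over the list alone). Arc stood at -2.14 ± 0.37 and Npas4 at -0.90 ± 0.23. Of 12 chemoreceptors, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). For each of these counts of 0, edgeR gave 0 at an unadjusted p under 0.05 and DESeq2 called 0. With no filter on low counts, 0 chemoreceptors were higher and 3 lower; with only the 2 classes compared in the model, 2 were higher and 3 lower.

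Neuroblast-like nuclei were compared with granule-like nuclei, the class into which most newborn neurons of the bulb mature. Among the list genes named, the largest rise was that of Prokr2, a prokineticin receptor needed for the migration of newborn bulb neurons and of GnRH neurons, at 68.0 ± 24.8 against 0.881 ± 0.0754 CPM (log2 fold change 6.20 ± 0.42). The glycine receptor subunit Glra2 (91.6 ± 13.2 against 9.69 ± 0.886 CPM; 3.23 ± 0.26), the potassium channels Kcnk2 (66.9 ± 12.4 against 5.81 ± 0.451 CPM; 3.50 ± 0.30), Kcnmb2 (91.2 ± 97.0 against 12.7 ± 1.18 CPM; 2.71 ± 0.38) and Kcnn3 (1.86 ± 0.31), Qrfpr (10.8 ± 8.47 against 0.875 ± 0.0711 CPM; 3.47 ± 0.77), Pde1c (2.72 ± 0.29), Chd7 (240.3 ± 2.09 against 67.1 ± 9.84 CPM; 1.85 ± 0.14), Gipr (1.82 ± 0.33) and the G protein Gnai2 (1.37 ± 0.30) were higher as well.

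Lower in neuroblast-like nuclei were the receptors Crhr1, of corticotropin-releasing hormone (17.0 ± 5.74 against 104 ± 9.90 CPM; -2.65 ± 0.26), Cckbr, of cholecystokinin (-2.87 ± 0.44), Tacr1 (21.2 ± 11.7 against 144 ± 11.8 CPM; -2.83 ± 0.29), Oprd1 (-2.80 ± 0.34), Npffr2 (-2.73 ± 0.29) and the histamine receptor Hrh2 (-2.66 ± 0.44). Trhr gave 0 against 613 UMIs and was at least 4.84-fold lower against 3 counts over the class sum. The immediate early gene Nr4a1 stood at 9.54 ± 4.36 against 86.7 ± 2.35 CPM (-3.23 ± 0.36). Junb gave 3 against 868 UMIs, a ratio of 6.86 (95% interval 2.34 to 33.3), and Arc 3 against 841 UMIs, a ratio of 6.64 (95% interval 2.27 to 32.3). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the 20 genes lay between 3.64e-14 for Chd7 and 0.00136 for Junb, each in the same direction in 2 of 2 libraries. Nos1 (-1.33 ± 0.29) was lower, while Pgr stood at 11.8 against 20.6 CPM and Esr1 gave 3 against 210 UMIs, with no call. The adjusted p was 4.42e-04, 0.270 and 0.565 by the same edgeR test.

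With equal numbers of nuclei at equal depth, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment no longer called Kcnn3 (1.73, adjusted p = 0.221), Gnai2 (1.75, 0.159), Cckbr (-2.35, 0.212) and Nos1 (-1.80, 0.0842) in neuroblast-like nuclei. Over nuclei with at least 1000 genes the same edgeR test no longer called Junb (-0.51, 0.508) and Arc (-0.67, 0.244). Without library 2 and without library 1, the log2 ratios were 6.02 and 5.39 for Prokr2, 2.11 and 3.71 for Qrfpr, 0.91 and 3.53 for Kcnmb2, -4.33 and -1.93 for Cckbr, -2.30 and -3.46 for Npffr2, -1.94 and -4.14 for Hrh2 and -3.55 and -2.19 for Arc.

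Over the 11 lists, 18 of 232 genes were higher and 84 lower in neuroblast-like nuclei, and 130 were not past the threshold (22 and 91 adjusted over the list alone). Potassium channels were lower for 26 of 59 and higher for 4 (6 higher and 28 lower adjusted over the list alone). Among those lower were Kcnh1 (42.6 ± 3.70 against 253 ± 26.5 CPM; -2.55 ± 0.23) and Kcnt2 (-2.19 ± 0.26). Glutamate receptors were lower for 9 of 24 and higher for 2 (2 higher and 11 lower adjusted over the list alone). Among those lower were Gria3 (-1.64 ± 0.22) and Grik4 (-2.40 ± 0.50). GABA and glycine receptors were lower for 8 of 19 and higher for 2 (2 higher and 9 lower adjusted over the list alone). Gabra5 stood at -1.44 ± 0.14 and Gabrd at -1.58 ± 0.34. Sodium, calcium, HCN and TRP channels were lower for 10 of 34 and higher for 1 (2 higher and 10 lower adjusted over the list alone). Of neuronal sodium channels, Scn2a stood at 116 ± 13.9 against 356 ± 16.0 CPM (-1.62 ± 0.15) and Scn1a at -1.12 ± 0.20. Peptide receptors were lower for 9 of 28 and higher for 3 (3 higher and 9 lower adjusted over the list alone). Monoamine and acetylcholine receptors were lower for 6 of 16 and higher for 0 (0 higher and 6 lower adjusted over the list alone). Chrm3 stood at -1.99 ± 0.34 and Adra1a at -1.83 ± 0.17.

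Steroid and metabolic hormone genes were lower for 4 of 11 and higher for 1 (1 higher and 4 lower adjusted over the list alone). The mineralocorticoid receptor Nr3c2 stood at 164 ± 30.4 against 458 ± 18.9 CPM and Ghr at 119 ± 31.2 against 330.3 ± 16.0 CPM. Peptide precursors were lower for 2 of 9 and higher for 0 (0 higher and 2 lower adjusted over the list alone): Penk at -2.16 ± 0.37, and Scg2 at -1.64 ± 0.29, with log2 ratios of -1.21 and -2.54 without library 2 and without library 1. Genes of GnRH neuron development were 3 of 17 higher and 3 lower (3 and 3 adjusted over the list alone). Prokr2 and Chd7 were higher, and Fgfr1, a fibroblast growth factor receptor, stood at -2.01 ± 0.28. Chemosensory transduction genes were 3 of 6 higher and 0 lower (3 and 1 adjusted over the list alone). The G protein Gnao1 stood at 576 ± 15.4 against 239.9 ± 15.2 CPM (1.27 ± 0.13). Immediate early genes were lower for 7 of 11 and higher for 0 (0 and 7 adjusted over the list alone), Npas4 among them at -2.23 ± 0.40. Of 12 chemoreceptors, 0 were higher and 0 lower (0 and 0 adjusted over the list alone). At an unadjusted p under 0.05, edgeR gave 1 transduction gene lower and 0 genes for each of the other counts of 0, and DESeq2 called 0 in each. Without the filter on low counts, and again with only the 2 classes compared in the model, 0 chemoreceptors were higher and 2 lower.

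**Figure D4:**
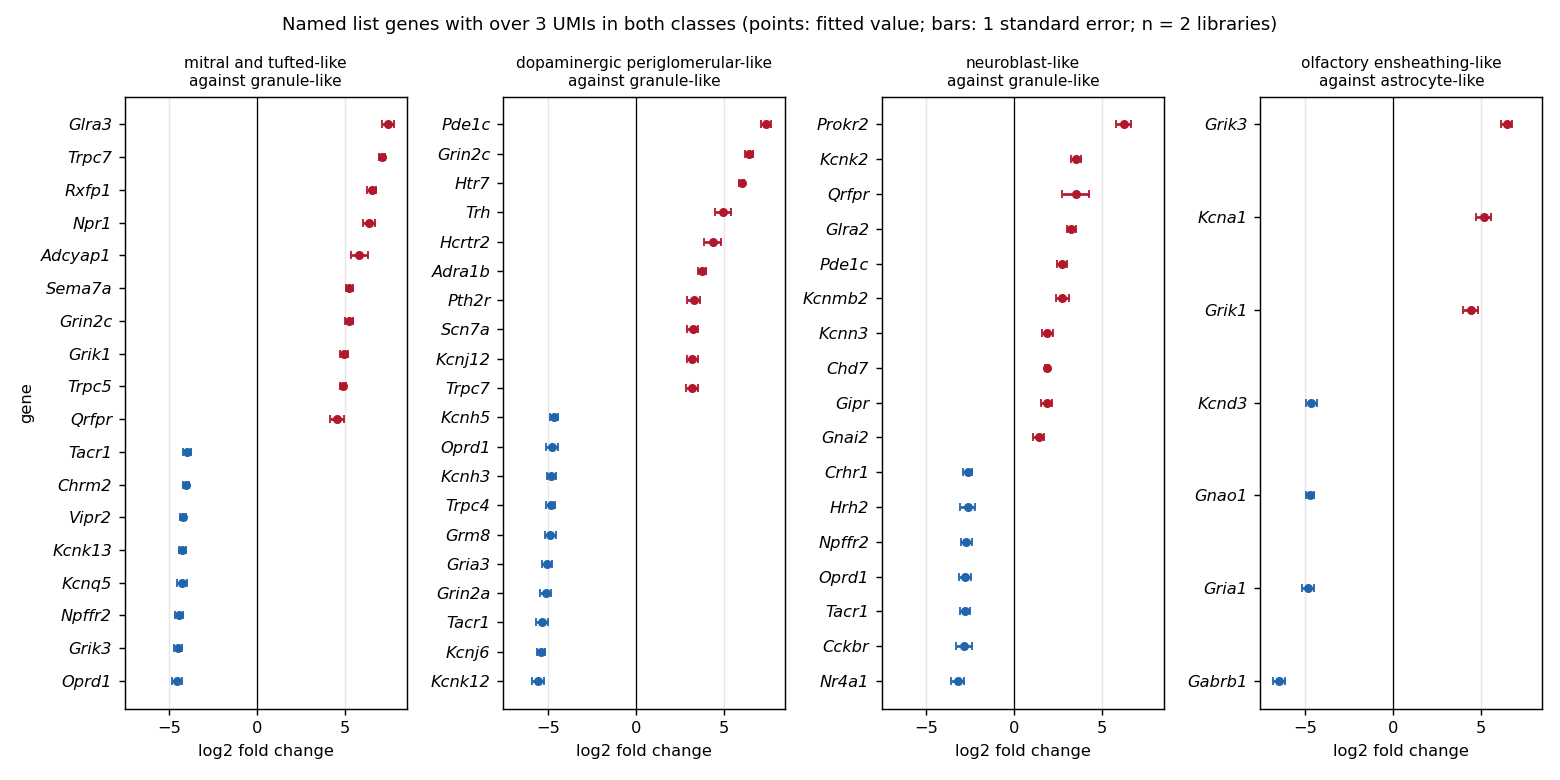
Log2 fold change (± SE) of the named list genes with more than 3 UMIs in both classes, for each of the 4 class comparisons, on a shared axis; points are fitted values from 2 libraries, and positive values are higher in the class named first. Pde1c in dopaminergic periglomerular-like nuclei, at 7.38, and Glra3 in mitral and tufted-like nuclei, at 7.42, lie furthest to the right.

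Olfactory ensheathing-like nuclei were compared with astrocyte-like nuclei, another glia-like class of the bulb. They were higher in the kainate receptor subunits Grik3 (781 ± 62.5 against 9.28 ± 4.54 CPM; log2 fold change 6.45 ± 0.29) and Grik1 (575 ± 129 against 27.5 ± 11.1 CPM; 4.41 ± 0.41), and in the potassium channel Kcna1 (155 ± 51.3 against 4.64 ± 2.27 CPM; 5.15 ± 0.43). Htr7 gave 182 against 3 UMIs, a ratio of 93.4 (95% interval 31.4 to 457). Npy, the precursor of neuropeptide Y, gave 103 against 3 UMIs, a ratio of 52.8 (95% interval 17.6 to 260.4), and the potassium channel Kcnj2 gave 14 against 1 UMIs, a ratio of 21.5 (95% interval 3.28 to 911). Against 3 counts over the class sum of astrocyte-like nuclei, which had 0 UMIs of each, Kcnn4, a calcium-activated potassium channel, was at least 15.9-fold higher (31 UMIs), Agt, the angiotensin precursor, at least 7.18-fold (14 UMIs) and the potassium channel Kcnk5 at least 4.62-fold (9 UMIs).

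Lower in ensheathing-like nuclei were the GABA receptor subunit Gabrb1 (49.8 ± 4.41 against 4453 ± 12.9 CPM; -6.48 ± 0.32), the AMPA receptor subunit Gria1 (72.8 ± 57.9 against 1993 ± 18.6 CPM; -4.83 ± 0.35), the G protein Gnao1 (40.9 ± 5.74 against 1059.6 ± 70.4 CPM; -4.70 ± 0.22) and the potassium channel Kcnd3 (-4.63 ± 0.29). At 3 UMIs or fewer in ensheathing-like nuclei, the ratios in favour of astrocyte-like nuclei were 71.1 (95% interval 24.1 to 346) for Kcnk2, 66.5 (95% interval 22.5 to 324) for Grin2c, 61.4 (95% interval 16.8 to 511) for Kcnn3, 39.0 (95% interval 6.74 to 1565) for the neuromedin receptor Nmur2 and 31.8 (95% interval 8.58 to 267) for Gabbr2. The histamine receptor Hrh1, at 0 against 33 UMIs, was at least 7.15-fold lower against 3 counts over the class sum. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the 20 genes lay between 2.91e-21 for Grik3 and 0.0279 for Kcnk5, each in the same direction in 2 of 2 libraries. In ensheathing-like against astrocyte-like nuclei, Pgr gave 4 against 5 UMIs, Esr1 0 against 5 UMIs and Nos1 1 against 5 UMIs, with no call. The DESeq2 Wald test did not call Kcnn4 (6.92, adjusted p = 0.591), Agt (5.81, 0.665) or Kcnk5 (5.20, 0.713). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the call of Kcnj2 was lost at equal nuclei and depth (2.36, adjusted p = 0.325). Without library 2 and without library 1, the log2 ratios were 5.81 and 4.17 for Kcna1, -5.94 and -4.14 for Gria1 and -5.57 and -4.11 for Kcnd3. For genes at 3 UMIs or fewer in a class they were 7.04 and 5.54 for Htr7, 6.20 and 4.75 for Npy, 5.28 and 3.13 for Kcnj2, 5.50 and 3.87 for Kcnk5, -6.81 and -5.44 for Kcnk2, -4.89 and -9.71 for Grin2c, -4.90 and -8.83 for Kcnn3, -3.86 and -7.47 for Nmur2 and -7.33 and -4.39 for Gabbr2.

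Over the 11 lists, 36 of 232 genes were higher and 44 lower in ensheathing-like nuclei, and 152 were not past the threshold (38 and 46 adjusted over the list alone). Glutamate receptors were 5 of 24 higher and 9 lower (5 and 9 adjusted over the list alone). Potassium channels were 9 of 59 higher and 15 lower (11 and 17 adjusted over the list alone). Sodium, calcium, HCN and TRP channels were 7 of 34 higher and 3 lower (8 and 3 adjusted over the list alone). Of calcium channels, Cacna1e stood at 2.77 ± 0.38 and Cacna1c at 426 ± 119.6 against 73.2 ± 34.9 CPM (2.58 ± 0.32). GABA and glycine receptors were 2 of 19 higher and 6 lower (2 and 6 adjusted over the list alone). The glycine receptor subunit Glrb stood at -3.64 ± 0.36. Monoamine and acetylcholine receptors were 3 of 16 higher and 2 lower (3 and 2 adjusted over the list alone). Htr1f stood at 2.27 ± 0.31. Peptide receptors were 2 of 28 higher and 3 lower (2 and 3 adjusted over the list alone). Calcrl, a receptor of the calcitonin family, gave 23 against 3 UMIs, a ratio of 11.8 (95% interval 3.56 to 61.4) (log2 ratios without library 2 and without library 1, 6.01 and 2.39), and the neurotensin receptor Ntsr2 stood at -4.42 ± 0.30.

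Peptide precursors were 2 of 9 higher, Npy and Agt, and 0 lower (2 and 0 adjusted over the list alone). Steroid and metabolic hormone genes were 2 of 11 higher and 2 lower (2 and 2 adjusted over the list alone). Ghr (792 ± 46.8 against 276 ± 16.6 CPM; 1.53 ± 0.17) was among those higher, and the thyroid hormone receptor Thrb (112 ± 32.9 against 644 ± 84.7 CPM; -2.53 ± 0.22) and Nr3c1 (-0.85 ± 0.22) were lower. Genes of GnRH neuron development were 3 of 17 higher and 3 lower (3 and 3 adjusted over the list alone). Nsmf stood at 2.12 ± 0.18, Flrt3 at 2.54 ± 0.35 and Ccdc141 at -1.68 ± 0.18. Chemosensory transduction genes were 1 of 6 higher, Pde1c at 2.52 ± 0.37, and 1 lower, Gnao1 (1 and 1 adjusted over the list alone). Immediate early genes were 0 of 11 higher and 0 lower (0 and 0 adjusted over the list alone). Chemoreceptors were 3 of 12 higher and 0 lower (3 and 0 adjusted over the list alone). Against 0 UMIs in astrocyte-like nuclei and 3 counts over that class sum, Olfr1271 was at least 40.5-fold higher (79 UMIs), Olfr142 at least 32.8-fold (64 UMIs) and Olfr1270 at least 9.23-fold (18 UMIs). The DESeq2 Wald test called 0 of these 3, with standard errors from 7.21 to 7.22. In the reference annotation on GRCm38.p6 the 3 genes lie near each other in 1 row, with Olfr1506, at 0 UMIs, between Olfr1270 and Olfr142. The nearby genes Olfr32, Olfr1269 and Olfr140 stood at 17.1, 8.54 and 7.12 CPM in ensheathing-like nuclei, over raw UMI totals. Shared reads or a single transcript over this row were not tested, so the 3 genes need not be separate signals. At an unadjusted p under 0.05, edgeR gave 1 peptide precursor lower, 0 chemoreceptors lower, and 1 immediate early gene higher and 1 lower, and DESeq2 called 0 in each.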

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

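The tests of this part were set down before their results were seen, except that the nuclei themselves were noticed first and the summed markers and both comparisons with random gene lists were chosen after the counts of the libraries were known. The result set apart here is a signal outside the classes compared: 33 olfactory sensory neuron-like nuclei in library 1, against 0 in library 2. The cell bodies of these neurons lie in the nasal epithelium, not in the bulb. They carried Stoml3 at 481 CPM (25 of 33 nuclei), Omp at 109.6 CPM (11 nuclei) and the odour transduction genes Gnal at 3759.9 CPM (33 nuclei), Ano2 at 1719.8 CPM (30 nuclei), Adcy3 at 767 CPM (29 nuclei) and Cngb1 at 211 CPM (18 nuclei), while Trpc2, the channel of vomeronasal neurons, had 0 UMIs in both libraries. Of the 33 nuclei, 23 held at least 3 UMIs of 1 chemoreceptor, with 21 different leading receptors (Olfr873, Olfr1213 and Olfr220 gave 54, 51 and 49 UMIs), and 0 nuclei held 3 UMIs of another receptor; the leading receptor took a median of 100% of the chemoreceptor UMIs.

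The tables argue against a like share of such nuclei in library 2, placed in another cluster or filtered out: over all barcodes the 7 markers summed to 3.04 CPM in library 2 against 6.01 in library 1 (ratio 0.506, 95% exact interval 0.403 to 0.633), and 106 of 10000 random lists of 7 genes matched on total UMIs gave a ratio as low (median 0.840). A smaller number stays open, since barcodes with at least 3 of the markers, 0 in library 2 and 7 in library 1, included only 6 of the 33 nuclei, so that count alone decides little. Nasal epithelium carried along with the tissue in library 1 stays open and is consistent with the counts of 13 genes of its supporting, basal and gland cells, 164 UMIs in library 1 and 61 in library 2, a ratio in CPM of 3.20 (95% exact interval 2.37 to 4.37; exact 2-sided binomial p = 1.72e-16; 4.67 against 1.46 CPM). This p and interval cover counting error only and set 1 library against 1 library, whose gene totals differ by more than that; of 10000 random lists of 13 genes matched on total UMIs, 0 gave a ratio as large (median 1.20, 95th percentile 1.66). The excess lay in the supporting cell genes Cyp2g1 (48 against 1 UMIs), Sec14l3 (43 against 0) and Cyp2a5 (18 against 0), whereas the basal cell gene Trp63 gave 44 and 42, the remaining genes gave at most 9, and whether the bulb itself expresses any of the 13 was not tested. No biological explanation was tested, since the design holds 1 group.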

How the results depend on the processing

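Of 328 values of the main results under alternatives, 293 stayed within the spread between libraries or within 1.5 times the count and 35 moved. The 293 include values that could not move. With 2 libraries, a single-library share or difference always lies within 1 SD of their mean. A count of 0 genes also stays at 0 when a library is left out. Of 1199 values for 96 gene results, 1183 were counted as unchanged, 16 lost the call and 0 reversed a call. Those of the 16 that are reported stand with their values beside the genes. The 96 values without library 1 and the 96 without library 2 carry no call. Named genes had been chosen for the same direction in both libraries, so these values could hardly reverse for them. Where a gene had no call, a change of direction was not counted. With equal nuclei and depth, which leaves fewer UMIs by construction, list genes higher and lower were 40 and 59 in mitral and tufted-like, 27 and 41 in dopaminergic periglomerular-like and 10 and 50 in neuroblast-like nuclei, and 4 chemoreceptors were higher in mitral and tufted-like nuclei, the only 4 of the 7 called that had counts enough to be tested there. Of the list genes called higher and lower, 61 of 83 and 74 of 90 (mitral and tufted-like), 45 of 59 and 71 of 85 (dopaminergic) and 15 of 18 and 71 of 84 (neuroblast) were tested there. The DESeq2 Wald test called 3 chemoreceptors higher in mitral and tufted-like and 0 in ensheathing-like nuclei. With no filter on low counts, 18 chemoreceptors were higher and 3 lower in mitral and tufted-like nuclei, and 3 and 2 were lower in the dopaminergic and neuroblast contrasts; with only the 2 classes compared in the model, these were 12 and 3, 3 and 2, and 2 were higher in dopaminergic nuclei. For these and the following shifts the cause was not tested. Shares moved for granule-like nuclei to 64.5% and 61.2% (resolutions 0.5 and 2.0), 62.5% (4000 variable genes), 59.0% (doublets kept), 61.5% and 62.6% (minimums of 1000 and 200 genes). Other GABAergic nuclei took 17.4% (resolution 0.5), 20.5% (doublets kept) and 17.4% (minimum of 1000 genes), dopaminergic nuclei 2.91% (doublets kept) and mixed vascular nuclei 0.828% (4000 variable genes) and 0.579% (minimum of 1000 genes). With called doublets kept no cluster was named microglia and macrophage-like, so that class has no value there (1.23% in the main run). Nuclei without a name, 0.0734% and 0.165% of libraries 1 and 2 in the main run, were 2.05% and 2.35% (resolution 2.0), 2.91% and 3.06% (doublets kept), 3.22% and 3.44% (minimum of 1000 genes), 0.986% and 1.14% (minimum of 200 genes) and 0.862% and 0.949% (4000 variable genes). Gnrh1 was in 0.0161% of nuclei at 2 or more UMIs and 0.135% after thinning, where 1 UMI is near the limit. The difference between Gnrh1 nuclei and others was 13.8 points for chemoreceptors with no matching, and for transduction genes 3.49 with no matching and 1.82 with every barcode matched on library and depth. Without the library block, list genes higher and lower were 77 and 87 (mitral and tufted-like), 55 and 79 (dopaminergic), 17 and 79 (neuroblast) and 36 and 44 (ensheathing), and chemoreceptors higher were 7 and 3 in the first and last of these; the pairing by library thus moved no count over 1.5 times. Leaving out a library leaves no test: of the genes called, those with the same direction in the single library were 81 to 83 and 90 to 90 (mitral and tufted-like), 59 and 85 (dopaminergic), 18 and 84 (neuroblast) and 36 and 44 (ensheathing) in either. Single-library shares ranged from 0 to 0.605% for sensory neuron-like nuclei and from 0.234% to 0.569% for Gnrh1. Gnrh1 gave 50 UMIs in all, so its shares rest on few counts.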

Other observations

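The tests in single clusters, the ratios of the receptor rows and of Gnrh1 between classes and the comparison of the Olfr111 split between clusters were chosen only after the data were examined. Several hormone and peptide receptor genes, left out of the clustering, stood high in single clusters of neurons. Esr2, an oestrogen receptor, reached 74.9 ± 4.65 CPM in cluster 20, of other GABAergic interneuron-like nuclei (log2 fold change 8.30 ± 0.57 against the mean of the other clusters, adjusted p 1.64e-19 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 382890 gene and cluster pairs). It was found in 29.4% and 26.6% of the cluster's nuclei in libraries 1 and 2, against 0.191% and 0% of glia-like and vascular-like nuclei (median depths 4849 and 4830.5 against 2890.0 and 2718 UMIs), and the next cluster, of dopaminergic nuclei, had 2.08 CPM. Tacr3, the neurokinin B receptor, reached 234 ± 49.6 CPM in granule-like cluster 27 (9.70 ± 0.36), in 47.6% and 57.1% of nuclei (median depths 6557.5 and 6335 UMIs) against 0.191% and 0.154% of the same glia. Trhr reached 131 ± 34.5 CPM in granule-like cluster 23 (7.16 ± 0.26; 39.2% and 28.4% of nuclei, at median depths of 5854.5 and 4989 UMIs, against 2.10% and 0.307%). Vip, the precursor of vasoactive intestinal peptide, reached 229 ± 59.4 CPM in cluster 26 (9.27 ± 0.39; 56.3% and 73.8% of nuclei, at median depths of 8622 and 6087 UMIs, against 0.382% and 0%), beside the glycine receptor subunit Glra1 at 413 ± 68.4 CPM. Oxtr, the oxytocin receptor, reached 16.3 ± 2.36 CPM in granule-like cluster 19 (5.16 ± 0.58).

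Some sex hormone receptor and immediate early genes were also uneven among clusters. Pgr stood at 65.3 ± 1.94 CPM in cluster 5, and Esr1 at 18.1 ± 0.528 CPM in granule-like cluster 15 (2.47 ± 0.38). In granule-like cluster 11, Arc stood at 57.9 ± 10.2 CPM (3.77 ± 0.20), Fosb at 30.2 ± 3.34 CPM (4.97 ± 0.34), Npas4 at 94.6 ± 2.79 CPM and Egr1 at 87.3 ± 13.1 CPM, with Egr1 close behind at 85.1 CPM in cluster 16. Only listed immediate early genes were left out of the clustering. Nr4a3, a relative of the listed Nr4a1 but not on the list, was among the 10 leading genes of cluster 11. The values there may thus not be independent of how the cluster was formed. Of 9030 pairs of list gene and cluster, 2581 were higher at the same threshold by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

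For chemoreceptor RNA in mitral and tufted-like nuclei, free RNA is argued against, since it gives like levels in every class and the summed CPM of Olfr110 to Olfr116 and Vmn1r206 to Vmn1r209 was 120 times (95% exact interval 83.1 to 181) that of glia-like and vascular-like nuclei. Sensory neuron nuclei or their RNA are also argued against: the 7 sensory neuron markers, summed, reached in mitral and tufted-like nuclei 0.315% of their CPM in sensory neuron-like nuclei, and library 2, with 0 such nuclei, had 573 and 156 CPM of the rows. A single transcript, or a single set of reads, spread over neighbouring copies stays open but is not shown: the share of Olfr111 in its row was lower in cluster 22 than in 24 in both libraries (55.2% and 60.1% in library 1, 61.5% and 70.8% in library 2), with Fisher's exact 2-sided p of 0.133 and 0.0812. A test over single nuclei took the 28 nuclei of cluster 22 in each library with at least 20 UMIs of the Olfr row. In them the split varied more than in most simulated sets (chi-square per degree of freedom 1.33 and 1.38, reached by 256 and 115 of 10000 sets). For these nuclei that excludes 1 fixed split at a limit of 0.05 and leaves it open at the limit of 0.01 set before that test. Reading both tests as 1 verdict was settled after their values were known. The Vmn1r row was not tested in this way. No biological explanation was tested, since the design holds 1 group.

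For the scatter of Gnrh1 UMIs over classes, free RNA stays open and is consistent with a ratio of Gnrh1 CPM, neuron-like over glia-like and vascular-like, of 0.393 (95% exact interval 0.167 to 1.13). Reads from the neighbouring gene Kctd9 cannot be told apart: 6 of the 48 nuclei held a Kctd9 UMI (12.5%, 95% exact interval 4.73 to 25.2) against 6.14% of matched nuclei, and 48 nuclei are too few to decide. Dock5, a neighbour on the other side of Gnrh1, gave 677 of its 729 UMIs in glia-like and vascular-like nuclei. Reads from Dock5 were not tested, so the glia-like share of Gnrh1 may not measure free RNA alone. No biological explanation was tested.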
